A study of Homo sapiens with 16 samples.

How the data were processed

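RNA-seq libraries from cultured human vascular smooth muscle cells were analysed, 16 in all, in 4 groups of 4: aortic and coronary artery cells, each on soft and on stiff hydrogel. Per the labels, cells were starved of serum for 48 h and kept for 24 h on fibronectin-coated hydrogels of 2 to 4 kPa (soft) or 20 to 25 kPa (stiff). RNA was depleted of ribosomal RNA and made into stranded libraries. The deposited files hold raw read counts per gene, which the authors made with STAR, SAMtools and HTSeq on the human genome build hg19. Versions, the annotation and the strand option of the counting step are not stated, so counts of antisense and overlapping RNAs may hold reads of the other strand. The authors' own DESeq2 results were not used here. Each file was checked to hold whole numbers for 57820 genes and 5 summary counts of reads not assigned to a gene.

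Ensembl gene identifiers were matched to a gene name table (51996 identifiers) and to GENCODE release 29 for gene types (52338 identifiers). Because the cells come from donors, 521 genes (Y-linked genes, XIST and TSIX) were left out of every table and test. No coordinates are given, since the files and the reference annotation are on different genome builds. The genes of type lncRNA, 13023 in the annotation, were treated as the class of long non-coding RNAs. Reads of replication-dependent histones and ribosomal proteins can be shared with near-identical copies or pseudogenes, so their values are uncertain.

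Counts assigned to genes ranged from 33.6 to 60.5 M per library, with a median of 44.2 M. A mean of 3 counts per library, taken as the floor, was 0.071 CPM, counts scaled to library size, in coronary cells. Reads carry no molecular identifiers, so the floor covers counting error only. P-values measure the spread between samples: the labels do not say whether replicates are separate cultures or donors. Every pair of libraries in a group differed by far more than counting error (chi-square per degree of freedom 26.52 to 264.51), so none is a copy of another. In each group replicates 1 and 2 differed least. Their values were 31.02 and 34.85 in aortic cells on soft and stiff matrix, and 30.06 and 26.52 in coronary cells. The reported tests treat the 4 libraries of a group as independent.

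Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, and the robust quasi-likelihood F test in 1 fit of all libraries with 12 residual degrees of freedom. The common biological coefficient of variation was 0.229. Of all genes, 17728 passed the filter and were tested, among them 13305 coding genes and 2161 long non-coding RNAs. Contrasts were stiff against soft within each artery, their mean, their difference (coronary minus aortic), and coronary against aortic on each matrix. Tests were two-sided, and a gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 fold changes are edgeR's, with a prior count; their SE is the absolute log2 fold change divided by the square root of F. Levels are CPM with TMM scaling, as mean ± SD over the 4 libraries of a group.

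The gene lists, 34 in all, included contractile smooth muscle, YAP/TAZ targets, MRTF/SRF targets, immediate early genes, S phase and DNA replication, G2 and mitosis, G1 cyclins, kinases and inhibitors, matrix structural genes, matrix cross-linking and remodelling, integrins and focal adhesions, cholesterol synthesis, fatty acid synthesis, inflammatory mediators, interferon-stimulated genes, hypoxia and glycolysis, unfolded protein and amino acid stress, TGF-beta and BMP pathway, osteochondrogenic genes, HOX genes, cardiovascular developmental factors, named long non-coding RNAs, replication-dependent histones, ribosomal proteins, mitochondrially encoded transcripts, the lncRNA class, and markers of endothelial, fibroblast, leukocyte, epithelial and mesothelial, cardiomyocyte, adipocyte, neural and glial, and pericyte cells. Of these, 31 were written out gene by gene (804 members, of which 798 were matched to an identifier; UHRF1, ACACA, CCL5, TP53COR1, RPPH1 and PECAM1 were not). The remaining lists were set by symbol pattern or gene type. A list needed 3 tested members. Lists can share genes, as the contractile, MRTF/SRF and YAP/TAZ lists do, so their results are not independent. The result of 1 further list, which counts among the 34, is not reported here.

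Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, which asks whether members move more than other genes, adjusted over the 34 lists in each comparison. The same test was then run with the correlation estimated from the data, and fry was run beside it, which asks whether a list's genes move on balance in 1 direction. The groups, contrasts, tests, lists, naming rule and most alternative settings were chosen before the data were examined. The naming rule took, for each stiffness comparison and for coronary against aortic cells on soft matrix, the 10 largest rises and 10 largest falls among changed genes with a mean of at least 1 CPM, groups that do not overlap and a gene symbol that is no clone or pseudogene name. For the difference of responses it took up to 5 genes each way without the overlap condition, and for long non-coding RNAs the 10 largest each way among those changed alike in both arteries. In addition, members of the lists are named as examples.

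Alternatives were RLE and upper-quartile factors, library size only, no low-count filter, a stricter filter (1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom, only the 8 libraries compared, a replicate block across all 16 libraries or within each artery, and each library left out in turn. Chosen after seeing the data were a term for replicates 1 and 2 against 3 and 4, the list tests with a block within each artery, and the list tests without Coronary-Stiff replicate 4. No label says what a replicate number stands for, so no block was used in the reported fit. Values within replicates 1 and 2 and within replicates 3 and 4 come from a fit of all 16 libraries, chosen after the results were seen. It treats the pairs of each group as separate groups with shared scaling and spread, so the pairs are not independent analyses. In coronary cells the deviations of soft and stiff libraries of the same number from their group means correlated in each of the 4 pairs (0.152, 0.266, 0.118 and 0.307), so these numbers were taken to pair the libraries, on the data alone. In no other combination of groups did all 4 pairs lie above 0.1. The correlations were low, and Coronary-Soft replicate 1 matched Coronary-Stiff replicate 2 best.

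The pipeline was tested on simulated data made from these libraries with 200 genes changed in each comparison. edgeR recovered 57% of changes of 1 and 94% of changes of 2 on the log2 scale in aortic cells with 9 false calls, and 51% and 79% in coronary cells with 4. For the difference of responses it recovered 22% and 67% with 2 false calls, and DESeq2 recovered 36% and 73% with 18 false calls. In the aortic comparison, the only one in which lists were simulated, 0 of 20 unchanged lists of random genes passed camera's threshold. Simulated genes were drawn independently, so this result cannot speak to camera on lists whose members move together. Simulated libraries were drawn independently too, with only 200 of 17728 genes changed. In the data 29.9% of genes were called in aortic and 41.6% in coronary cells. The shares recovered and the false calls may therefore not hold for the data.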

Results

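Vascular smooth muscle cells, the contractile cells of the artery wall, were taken from human aorta and coronary artery and grown on soft (2 to 4 kPa) or stiff (20 to 25 kPa) fibronectin-coated hydrogels, and their RNA was sequenced. The 16 libraries form 4 groups of 4 replicates, named here by artery and matrix. Counts assigned to genes ranged from 39.6 to 60.5 M in aortic cells on soft matrix and from 37.2 to 53.9 M on stiff matrix. In coronary cells they ranged from 33.6 to 51.9 M on soft and from 39.1 to 56.4 M on stiff matrix. In a multidimensional scaling of all libraries, the 2 axes carried 36% and 28.4% of the variance. In Coronary-Stiff replicate 4, 4.95% of reads fell outside annotated exons and 0.11% of gene counts were mitochondrial, the lowest of the 16 libraries. It also had the fewest genes with a count, 21652. Unless stated otherwise, log2 fold changes are given ± SE and CPM values ± SD, with n = 4 libraries per group.

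**Figure D1:**
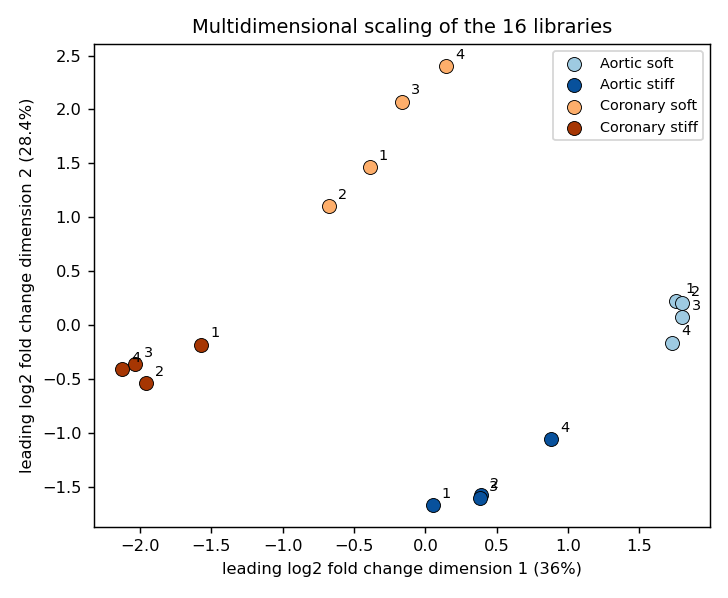
Multidimensional scaling of the 16 libraries on log2 CPM, with the leading axis (36% of the variance) across and the next (28.4%) up; each point is a library, coloured by artery and matrix.

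The comparison of stiff with soft matrix in aortic cells asks which transcripts depend on the stiffness under the cell. Genes of cell division rose, and G2 and mitosis had the highest median of the 34 lists. CDC20 (ENSG00000117399.9), an activator of the complex that drives exit from mitosis, rose from 22.4 ± 13.6 to 217 ± 48.3 CPM, a log2 fold change of 3.28 ± 0.533. All 39 tested members of the G2 and mitosis list rose, with a median of 2.66, among them the cyclin gene CCNB1 by 2.98 ± 0.459 and the proliferation marker MKI67 by 1.88 ± 0.532. Of the 41 S phase and DNA replication genes 40 rose (41 adjusted over the list alone; median 1.72), such as RRM2, which makes deoxynucleotides, by 2.82 ± 0.568 and MCM2 of the replicative helicase by 1.67 ± 0.266. Of 32 replication-dependent histones 31 rose (31 adjusted over the list alone; median 2.03), and 45 of 77 ribosomal protein genes rose by less (56 adjusted over the list alone; median 0.37). Against other genes, camera gave adjusted p = 1.61e-25 for G2 and mitosis, 8.72e-25 for S phase, 1.9e-28 for histones and 6.43e-12 for ribosomal proteins. With an estimated correlation these became adjusted p = 0.378, 0.378, 0.302 and 0.429. The G2 and mitosis median was 3.46 within replicates 1 and 2 and 2.11 within replicates 3 and 4.

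Of 28 contractile smooth muscle genes 9 rose and 2 fell in aortic cells on stiff matrix (11 and 2 adjusted over the list alone; median 0.44). TAGLN, which encodes an actin-binding protein of smooth muscle, went from 166 ± 16.3 to 749 ± 153 CPM, CNN1 (calponin) rose by 1.61 ± 0.395 and TPM1 (tropomyosin) by 1.81 ± 0.281. ACTA2, the smooth muscle actin gene, did not pass, at 1.22 ± 0.466 (adjusted p = 0.0606). With the replicate pairs fitted as separate groups, a fit chosen after the results were seen, ACTA2 was at 1.34 in replicates 1 and 2 (adjusted p = 0.00618). In replicates 3 and 4 ACTA2 was at 1.06 (adjusted p = 0.0397). That fit takes differences between the pairs out of the spread. The transcription factors MRTF/SRF and YAP/TAZ respond to actin tension. Of 29 MRTF/SRF targets 13 rose and 1 fell (16 and 1 adjusted over the list alone; median 0.50). Of 22 YAP/TAZ targets 11 rose and 2 fell (13 and 3 adjusted over the list alone; median 0.67), with ANKRD1 (ENSG00000148677.6) up by 3.45 ± 0.788, CCN2 by 1.37 ± 0.253 and CCN1 by 0.97 ± 0.216. ANKRD1, CCN2 and CCN1 are also in the MRTF/SRF list, which shares TAGLN, CNN1, TPM1 and ACTA2 with the contractile list. All 6 epithelial and mesothelial markers, mostly keratins, rose (6 adjusted over the list alone; median 1.44), with KRT7 at 19.1 ± 3.8 CPM on soft and 137 ± 22.0 on stiff matrix. Camera gave adjusted p = 0.0126 for contractile, 6.51e-05 for MRTF/SRF, 0.003 for YAP/TAZ and 7.4e-05 for epithelial genes. With an estimated correlation the values were adjusted p = 0.617, 0.429, 0.378 and 0.378.

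Of 49 matrix structural genes 19 fell and 3 rose on stiff matrix in aortic cells (23 and 3 adjusted over the list alone; median −0.56). COL15A1, a basement membrane collagen, fell by 2.06 ± 0.256, and COL3A1 of fibrillar collagen by 0.93 ± 0.223, while COL1A1 stood at −0.76 ± 0.489 (adjusted p = 0.261). Of 29 TGF-beta and BMP genes 15 fell and 1 rose (16 and 1 adjusted over the list alone; median −0.63). The growth factor gene TGFB3 was at 50.5 ± 15.8 CPM on soft and 6.10 ± 4.27 on stiff matrix, and INHBA fell by 1.62 ± 0.263. Of 13 fibroblast markers 7 fell and 2 rose (8 and 2 adjusted over the list alone; median −0.62), such as FAP, which fell by 1.31 ± 0.242, and THY1, which rose by 1.21 ± 0.306. These 3 lists had camera adjusted p = 0.000113, 0.000298 and 0.00716, and adjusted p = 0.429, 0.378 and 0.302 with an estimated correlation. Of 33 inflammatory mediators 13 fell and 4 rose (13 and 5 adjusted over the list alone; median −0.71, adjusted p = 0.0666). PTGS2, the inducible prostaglandin synthase, fell by 2.01 ± 0.312 and the chemokine gene CXCL1 rose by 2.14 ± 0.466. Among 41 matrix cross-linking and remodelling genes 16 fell and 3 rose (17 and 4 adjusted over the list alone; median −0.45, adjusted p = 0.0575), with the stromelysin gene MMP10 down by 2.49 ± 0.665 and the lysyl oxidase gene LOX up by 1.32 ± 0.308. Of 27 immediate early genes 9 fell and 3 rose (10 and 4 adjusted over the list alone; median −0.34, adjusted p = 0.0571). Of 16 osteochondrogenic genes 4 fell (4 down and 1 up adjusted over the list alone; median −0.55, adjusted p = 0.0571).

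Across all genes, edgeR called 5292 of 17728 (29.9%) as changed in aortic cells, 2598 higher and 2694 lower on stiff matrix, with a median size of 0.837 on the log2 scale. Of these, 1076 rose and 954 fell at least 2-fold. Besides cell division genes, the genes named by the rule included APLN (ENSG00000171388.9), which encodes the peptide apelin, up by 3.24 ± 0.34, and MGAM up by 3.42 ± 0.428. Among the falls were NFATC2, a calcium-regulated transcription factor, by 3.24 ± 0.452 and the aldo-keto reductase gene AKR1B10 by 3.21 ± 0.461. Within replicates 1 and 2, 3926 genes passed and within replicates 3 and 4, 1761, with 1635 in both in the same direction. By camera 12 of the 34 lists passed, 9 up and 3 down, by fry 18, and with an estimated correlation 0. At an unadjusted p under 0.05, 7223 genes passed. Other splits of the same 8 libraries gave up to 16 lists.

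**Figure D2:**
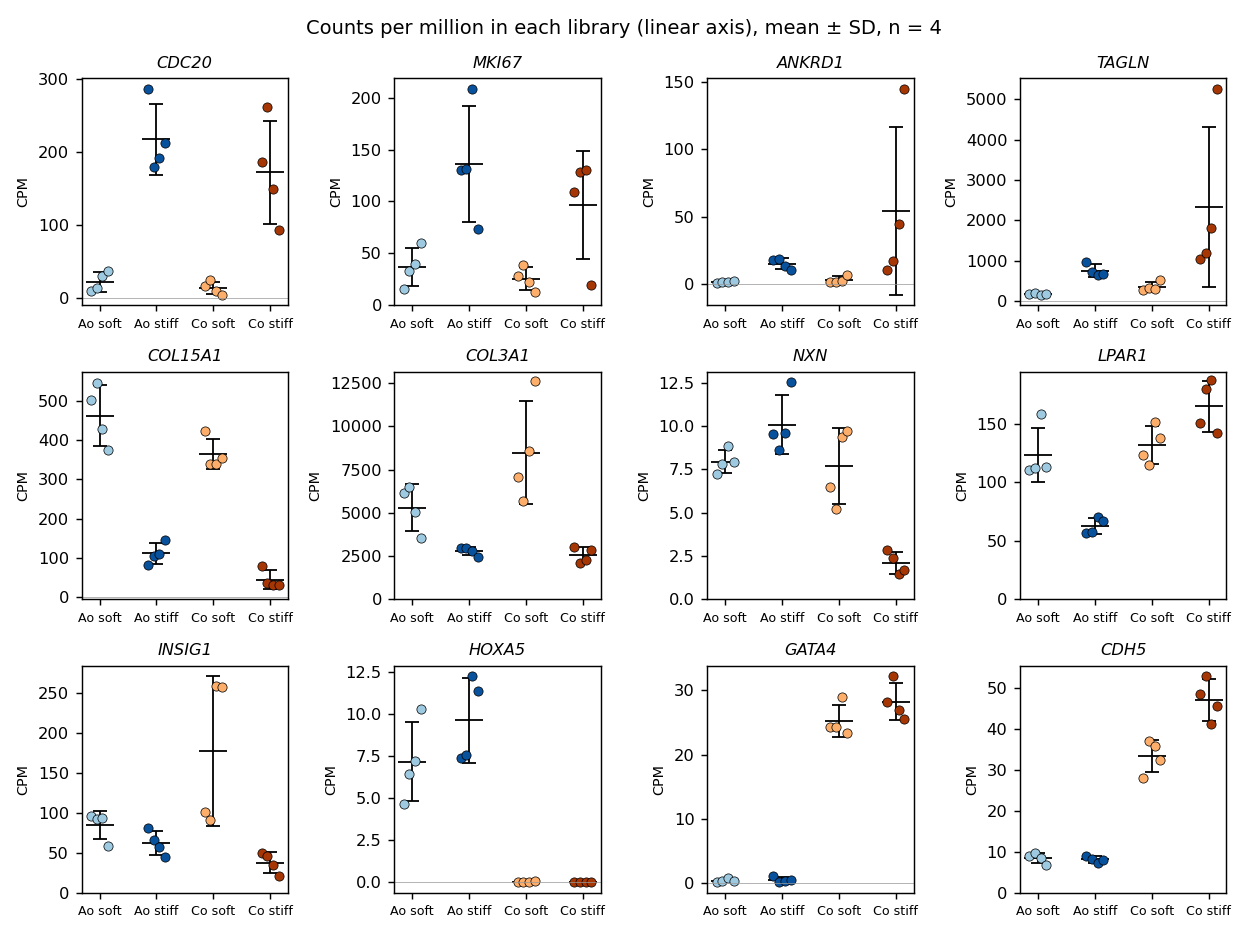
CPM of 12 genes (CDC20, MKI67, ANKRD1, TAGLN, COL15A1, COL3A1, NXN, LPAR1, INSIG1, HOXA5, GATA4 and CDH5) in each library, by group, with the mean and SD over the 4 libraries as a bar and whiskers. CDC20 lies between 93.22 and 286.65 CPM in stiff libraries and between 4.19 and 37.36 in soft ones.

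The same comparison in coronary cells asks whether cells of another artery depend on stiffness too. Cell division genes rose here too: all 39 G2 and mitosis genes (39 adjusted over the list alone; median 2.69), 38 of 41 S phase genes (39 adjusted over the list alone; median 1.45) and 31 of 32 histones (31 adjusted over the list alone; median 1.93). CDC20 went from 13.5 ± 8.66 to 173 ± 70.5 CPM and PLK1, a mitotic kinase, rose by 3.42 ± 0.476. Of 77 ribosomal protein genes 68 rose (68 adjusted over the list alone; median 0.59). In this order the lists had camera adjusted p = 2.94e-18, 2.37e-13, 8.29e-23 and 5.94e-18, and adjusted p = 0.366, 0.366, 0.171 and 0.366 with an estimated correlation. Medians within replicates 1 and 2 and within replicates 3 and 4 were 2.48 and 3.26 for G2 and mitosis and 0.36 and 0.78 for ribosomal proteins.

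In coronary cells 18 of 28 contractile genes rose and 2 fell (20 and 2 adjusted over the list alone; median 1.04). TAGLN rose by 2.74 ± 0.422, from 348 ± 114 to 2322 ± 1990 CPM, and CNN1 by 2.10 ± 0.401, while ITGA8, an integrin of smooth muscle, fell by 3.03 ± 0.558. Of 29 MRTF/SRF targets 22 rose and 1 fell (22 and 1 adjusted over the list alone; median 0.79), and of 22 YAP/TAZ targets 10 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.51). All 6 epithelial and mesothelial markers rose (6 adjusted over the list alone; median 2.57), with KRT14 at 0.252 ± 0.186 CPM on soft and 8.30 ± 8.80 on stiff matrix. Camera gave adjusted p = 0.000531 for contractile, 2.45e-06 for MRTF/SRF, 0.0127 for YAP/TAZ and 5.97e-07 for epithelial genes. The values were adjusted p = 0.394, 0.366, 0.366 and 0.171 with an estimated correlation. In Coronary-Stiff replicate 4 TAGLN stood at 5262 CPM, ANKRD1 at 145 CPM and MKI67 at 19.9 CPM. Without that library the log2 fold change of CNN1 was 1.33, of MYL9 1.29 against 2.14 ± 0.497, and of ACTA2 1.02 against 1.85 ± 0.469, all past the threshold. For ACTA2 the difference of the responses between arteries had adjusted p = 0.899. Without that library the contractile median was 0.586, with 16 members up and 2 down. The contractile median was 0.47 within replicates 1 and 2 and 1.42 within replicates 3 and 4.

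Of 49 matrix structural genes 35 fell and 1 rose in coronary cells (36 and 2 adjusted over the list alone; median −1.01). COL15A1 fell by 3.01 ± 0.267, COL3A1 by 1.74 ± 0.228 and COL1A2 by 1.41 ± 0.209, and FN1 (fibronectin) by 1.31 ± 0.262. Of 29 TGF-beta and BMP genes 19 fell and 1 rose (19 and 1 adjusted over the list alone; median −0.79), with TGFB2 down by 2.18 ± 0.216. Of 13 fibroblast markers 8 fell and 2 rose (9 and 2 adjusted over the list alone; median −0.73). Among 41 cross-linking and remodelling genes 22 fell and 6 rose (24 and 7 adjusted over the list alone; median −0.67), such as the collagenase gene MMP1, which fell by 2.22 ± 0.419, and TIMP3, a protease inhibitor, which rose by 1.49 ± 0.212. Of 33 inflammatory mediators 21 fell and 5 rose (21 and 5 adjusted over the list alone; median −1.15), with PTGS2 down by 2.95 ± 0.323. In this order the 5 lists had camera adjusted p = 2e-12, 1.01e-07, 0.0136, 0.000376 and 0.000417, and adjusted p = 0.171, 0.171, 0.171, 0.366 and 0.366 with an estimated correlation. The matrix structural median was −0.79 within replicates 1 and 2 and −1.20 within replicates 3 and 4.

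Among further lists, 13 of 27 immediate early genes fell and 5 rose in coronary cells (15 and 5 adjusted over the list alone; median −0.49), with NR4A1 down by 2.36 ± 0.357 and KLF2, a flow-responsive transcription factor, up by 2.53 ± 0.277. Of 16 osteochondrogenic genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; median −1.07), among them MGP, an inhibitor of calcification, by a fall of 1.89 ± 0.265. Of 34 cardiovascular developmental factors 13 fell and 1 rose (13 and 1 adjusted over the list alone; median −0.17), such as the Notch ligand gene JAG1, down by 1.28 ± 0.192. These 3 had camera adjusted p = 0.0207, 0.0187 and 0.0314, and adjusted p = 0.383, 0.366 and 0.502 with an estimated correlation. Without Coronary-Stiff replicate 4 the developmental list had adjusted p = 0.134. Of 25 cholesterol synthesis genes 12 fell and 2 rose (13 and 2 adjusted over the list alone; median −0.73, adjusted p = 0.0459, fry adjusted p = 0.156). Of 11 fatty acid synthesis genes 6 fell and 1 rose (6 and 1 adjusted over the list alone; median −0.61, adjusted p = 0.0273). HMGCS1 of the sterol pathway fell by 1.94 ± 0.365, its regulator INSIG1 by 2.24 ± 0.353 and the desaturase gene SCD by 3.11 ± 0.661. These lists had adjusted p = 0.725 and 0.383 with an estimated correlation. In aortic cells 3 cholesterol genes rose and 2 fell (3 and 2 adjusted over the list alone; median −0.12, mean −0.03, adjusted p = 0.584 with the test pointing up), 1 fatty acid gene rose and 1 fell (median −0.33, adjusted p = 0.336), and 3 developmental factors rose and 7 fell (4 and 7 adjusted over the list alone; median −0.19, adjusted p = 0.336). The cholesterol median was −0.05 within replicates 1 and 2 and −1.14 within replicates 3 and 4, and that of fatty acid synthesis −0.26 and −0.85.

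In all, edgeR called 7375 genes (41.6%) as changed in coronary cells, 3730 higher and 3645 lower on stiff matrix, with a median size of 0.886 on the log2 scale. Of these, 1388 rose and 1777 fell at least 2-fold. Rule-named genes included KRT34, a keratin gene, at 3.91 ± 2.28 CPM on soft and 85.7 ± 104 on stiff matrix (238 in Coronary-Stiff replicate 4). Another was TMOD1 (ENSG00000136842.9), whose protein caps actin filaments, at 2.02 ± 1.83 CPM on soft and 0.0292 ± 0.0359 on stiff matrix. NPPB, a natriuretic peptide gene, rose by 4.04 ± 0.934, and by 2.27 without Coronary-Stiff replicate 4. EGR2, an immediate early transcription factor, fell by 4.42 ± 0.433. Within replicates 1 and 2, 2650 genes passed and within replicates 3 and 4, 6557, with 2383 in both in the same direction and 1 in opposite directions. By camera 20 lists passed, 9 up and 11 down, by fry 25, and with an estimated correlation 0. At an unadjusted p under 0.05, 8802 genes passed. Without Coronary-Stiff replicate 4 the number of genes changed by stiff matrix in coronary cells was 7270, with 20 lists.

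**Figure D3:**
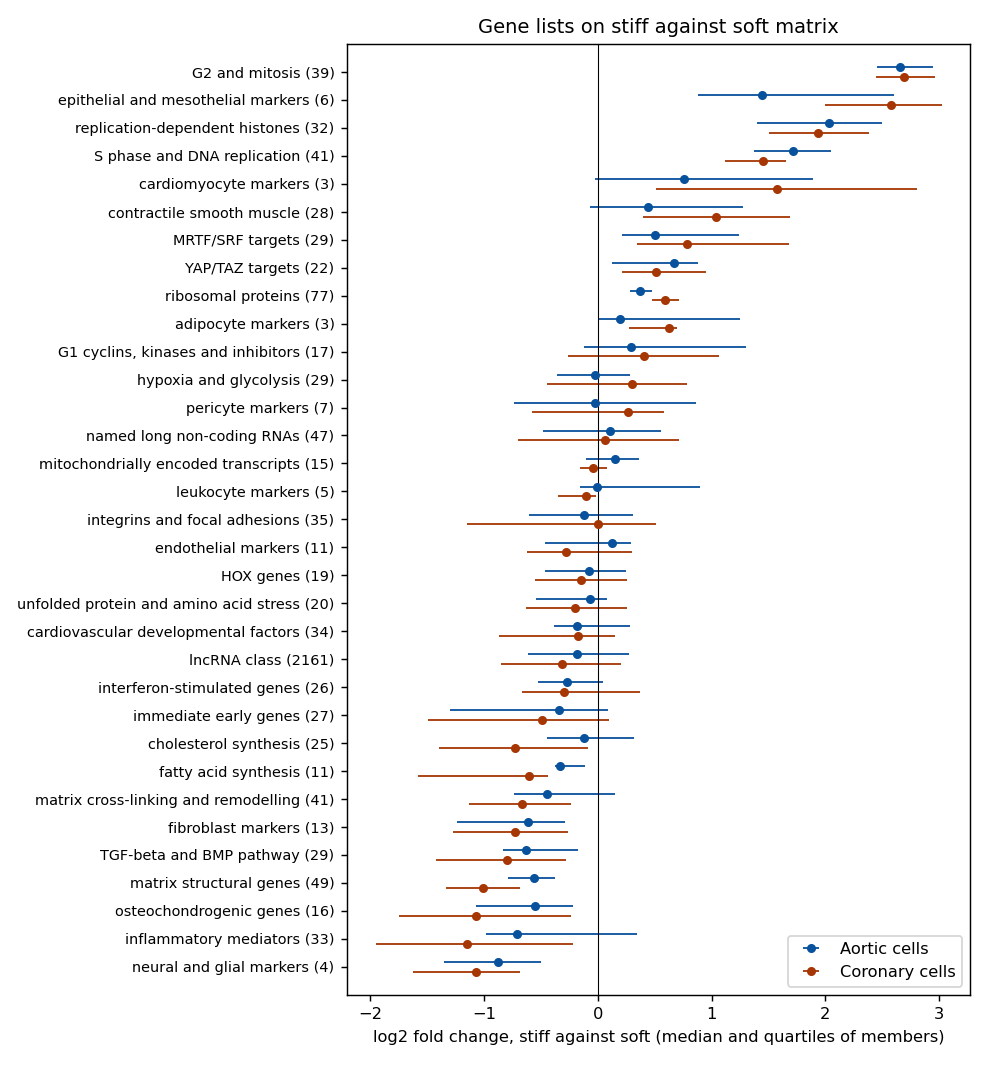
Median log2 fold change, with quartiles of the members, of 33 gene lists on stiff against soft matrix in aortic and coronary cells. The G2 and mitosis list reaches 2.66 in aortic and 2.69 in coronary cells, and matrix structural genes −0.56 and −1.01.

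Set side by side, the responses of both arteries shared most genes, which bears on whether there is a stiffness response of smooth muscle in general. Changed in the same direction in both were 4412 genes, 2263 up (547 expected of independent lists) and 2149 down (554 expected), and 4 genes changed in opposite directions. APLN rose by 3.24 ± 0.34 in aortic and 3.38 ± 0.314 in coronary cells, LOX by 1.32 ± 0.308 and 1.29 ± 0.308, and FAP fell by 1.31 ± 0.242 and 1.31 ± 0.242. Changed in aortic cells only were 876 genes and in coronary cells only 2959, which by itself shows no difference between the arteries. Across genes, which are not independent replicates, the log2 fold changes of both arteries had a Pearson correlation of 0.818 and a Spearman correlation of 0.806, and 82.6% of all genes had the same sign. The slope of coronary on aortic effects was 1.29 (1.16 to 1.41 with a library left out), but 0.854 within replicates 1 and 2 and 1.94 within replicates 3 and 4. Within replicates 1 and 2, 3926 genes passed in aortic and 2650 in coronary cells, and within replicates 3 and 4, 1761 and 6557. For the mean of both arteries 9158 genes (51.7%) passed, 4391 up and 4767 down, with 16 lists by camera (9 up and 7 down), 25 by fry and 0 with an estimated correlation. At an unadjusted p under 0.05, 10180 genes passed.

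**Figure D4:**
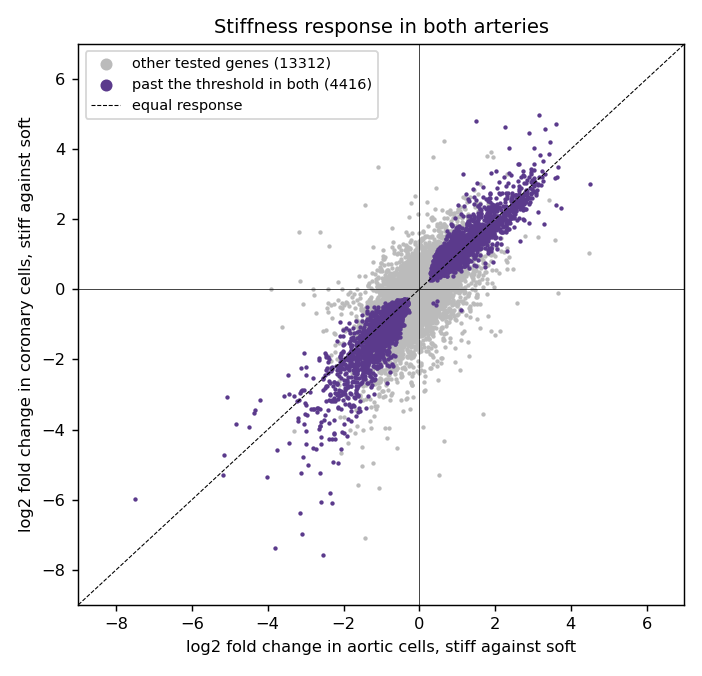
Log2 fold change on stiff against soft matrix in coronary cells (vertical) against aortic cells (horizontal), a point per gene. The genes changed in both arteries, 4412 in the same direction and 4 in opposite directions, are coloured and the others are grey.

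Whether the stiffness response itself differs between arteries was tested by the difference of the responses, coronary minus aortic. LPAR1 (ENSG00000198121.9), a receptor for lysophosphatidic acid, fell from 123 ± 23.3 to 62.7 ± 6.64 CPM in aortic cells, and was at 132 ± 16.3 and 165 ± 21.9 CPM on soft and stiff matrix in coronary cells (log2 fold change 0.32 ± 0.143, adjusted p = 0.0782). NXN (ENSG00000167693.12), which encodes nucleoredoxin, fell from 7.68 ± 2.21 to 2.09 ± 0.645 CPM in coronary cells and was at 7.94 ± 0.678 and 10.1 ± 1.71 CPM in aortic cells (adjusted p = 0.256). The difference of responses was 1.30 ± 0.203 for LPAR1 (adjusted p = 0.041) and −2.22 ± 0.321 for NXN (adjusted p = 0.0307). edgeR called these 2 genes and no others, limma-voom called 2 and DESeq2 41, and 1191 genes had an unadjusted p under 0.05 by edgeR. With 1 library left out the count was 0 for Aortic-Stiff replicates 1, 2 and 3, Aortic-Soft replicates 1 to 4, Coronary-Stiff replicates 2 and 3 and Coronary-Soft replicates 3 and 4. It was 1 without Coronary-Soft replicate 1 or 2, 3 without replicate 4 of Aortic-Stiff or Coronary-Stiff, and 8 without Coronary-Stiff replicate 1. With a replicate block within each artery the count was 0.

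As groups, 17 lists had a camera adjusted p under the threshold for this difference, 7 up and 10 down, although no member passed by itself over all genes. Matrix structural genes had a median difference of −0.42 (adjusted p = 1.2e-12; 1 down adjusted over the list alone), cholesterol synthesis genes −0.52 (adjusted p = 2.05e-07; 1 down adjusted over the list alone), ribosomal proteins 0.19 (adjusted p = 1.84e-07) and epithelial and mesothelial markers 0.95 (adjusted p = 0.000714; 2 up adjusted over the list alone). None of the lists passed with an estimated correlation (lowest adjusted p = 0.613) or by fry (lowest adjusted p = 0.576). Without Coronary-Stiff replicate 4 camera called 10 lists, without contractile genes (median −0.03, adjusted p = 0.935), MRTF/SRF targets (median −0.04, adjusted p = 0.706) and S phase genes (median −0.17, adjusted p = 0.905). The median difference of responses in replicates 1 and 2 and in replicates 3 and 4 was −0.13 and −0.73 for matrix structural, −0.16 and −0.93 for cholesterol synthesis, 0.02 and 0.36 for ribosomal, −0.02 and 1.55 for epithelial, −0.17 and 0.81 for contractile, −0.23 and 0.68 for MRTF/SRF and −0.80 and 0.44 for S phase genes. Across all genes the differences in these 2 pairs had a Pearson correlation of 0.0289.

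Long non-coding RNAs, the class named in the study's title, were counted over all genes tested. In aortic cells 330 of 2161 (15.3%) changed, 129 up and 201 down (84 up and 114 down adjusted over the class alone). In coronary cells 553 (25.6%) changed, 156 up and 397 down (117 up and 319 down adjusted over the class alone), and 236 changed in the same direction in both, 90 up and 146 down. CYTOR, at 20.9 ± 1.33 CPM on soft and 60.9 ± 10.1 on stiff matrix in aortic cells, rose by 1.54 ± 0.241 there and by 2.09 ± 0.244 in coronary cells, and MIR4435-2HG by 1.59 ± 0.223 and 1.81 ± 0.225. NORAD fell by 0.84 ± 0.178 and 0.93 ± 0.178, and PACERR, transcribed upstream of PTGS2, by 1.16 ± 0.296 and 2.22 ± 0.317. SENCR, an RNA of vascular cells, rose by 1.07 ± 0.221 in coronary cells and stood at 0.55 ± 0.223 in aortic cells (adjusted p = 0.0687), and the difference of the responses did not pass (adjusted p = 0.801). Of the RNAs named by the rule, LINC01111 (ENSG00000254300.1) had 0.342 ± 0.0982 and 2.65 ± 1.17 CPM on soft and stiff matrix in aortic cells and 0.779 ± 0.286 and 6.49 ± 2.85 in coronary cells. LINC01915 had 2.11 ± 0.721 and 0.412 ± 0.106 CPM in aortic cells and 0.758 ± 0.25 and 0.0859 ± 0.0608 in coronary cells.

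Called long non-coding RNAs were lower on stiff matrix more often than called coding genes, in 71.8% against 49.1% in coronary cells (Fisher exact p = 3.95e-25) and in 60.9% against 52.3% in aortic cells (Fisher exact p = 0.00245). These p-values treat genes as independent. Coding genes of matched abundance were lower in 68.4% and 62.5%. With replicate pairs as separate groups, 92 of the class were higher and 121 lower in aortic replicates 1 and 2. In aortic replicates 3 and 4 this turned to 46 higher and 38 lower. In coronary cells 50 were higher and 72 lower in replicates 1 and 2, and 146 and 339 in replicates 3 and 4. The class medians in these pairs were −0.22 and −0.13 in aortic and −0.24 and −0.38 in coronary cells. The class had a median log2 fold change of −0.31 in coronary cells (camera adjusted p = 0.0243, adjusted p = 0.452 with an estimated correlation) and −0.18 in aortic cells (camera adjusted p = 0.353). Of 47 named long non-coding RNAs 13 rose and 7 fell in aortic cells (15 and 7 adjusted over the list alone; median 0.11, adjusted p = 0.165). Of these, 11 rose and 12 fell in coronary cells (13 and 12 adjusted over the list alone; median 0.06, turning to −0.01 under upper-quartile factors; adjusted p = 0.627). Without Aortic-Stiff replicate 1 the aortic count of the class was 211, and with the stricter filter the coronary count was 316.

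Coronary cells were compared with aortic cells on each matrix to ask how the arteries differ at the same stiffness. The labels do not name the people the cells came from, so a difference between arteries may be one between people. HOX genes, which mark position along the body axis, were lower in coronary cells for most members: HOXA5 (ENSG00000106004.4) had 7.16 ± 2.36 CPM in aortic and 0.0245 ± 0.0374 in coronary cells on soft matrix, and 9.63 ± 2.53 and 0.0180 ± 0.0217 on stiff matrix. Of 19 HOX genes 15 were lower on soft (17 adjusted over the list alone; median −2.69, adjusted p = 2.93e-32) and 12 on stiff matrix (15 adjusted over the list alone; median −2.21, adjusted p = 3.35e-29). With genes at or under the floor of 3 counts per library set to their bound (9 genes on soft, 7 on stiff matrix), the medians were −2.27 and −1.77. This was the only list that also passed with an estimated correlation, at adjusted p = 0.000325 and 0.000207. The medians within replicates 1 and 2 and within replicates 3 and 4 were −1.89 and −3.11 on soft and −2.14 and −2.28 on stiff matrix.

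Cardiovascular developmental factors differed in both directions, with 9 higher and 7 lower in coronary cells on soft matrix (10 and 9 adjusted over the list alone) and 8 and 9 on stiff matrix (9 and 12 adjusted over the list alone). GATA4 (ENSG00000136574.13), a cardiac transcription factor, had 0.429 ± 0.272 CPM in aortic and 25.3 ± 2.49 in coronary cells on soft matrix, and TCF21, of the epicardial lineage, 1.56 ± 0.712 and 36.2 ± 4.95 CPM on stiff matrix. On soft matrix WT1 was higher in coronary cells by 4.03 ± 0.297, while MEIS1 was lower by a log2 fold change of −1.46 ± 0.169 and TBX1 had 1.15 ± 0.319 CPM in aortic and 0.0247 ± 0.0296 in coronary cells. The list had camera adjusted p = 0.0886 on soft matrix, where the median was −0.03 and the mean 0.29, and 0.684 on stiff matrix, where they were −0.10 and 0.08. Endothelial markers were higher for 6 of 11 genes on soft (6 adjusted over the list alone; median 0.60, adjusted p = 9.91e-06) and for 6 on stiff matrix (6 up and 2 down adjusted over the list alone; median 0.57, adjusted p = 3.03e-06). CDH5, the cadherin of endothelial junctions, had 8.48 ± 1.28 CPM in aortic and 33.4 ± 3.98 in coronary cells on soft matrix and KDR differed by 2.46 ± 0.399, while EMCN had 8.54 and 9.3 CPM. The endothelial list had adjusted p = 0.11 and 0.0753 with an estimated correlation.

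Of 49 matrix structural genes 22 were higher and 2 lower in coronary cells on soft matrix (29 and 2 adjusted over the list alone; median 0.67, adjusted p = 2.36e-11, adjusted p = 0.302 with an estimated correlation). FN1 was at 8275 ± 1110 CPM in aortic and 19520 ± 9940 in coronary cells and COL6A1 differed by 1.42 ± 0.249, whereas POSTN was lower by a log2 fold change of −3.10 ± 0.534. The median was 0.24 within replicates 1 and 2 and 0.89 within replicates 3 and 4. Cell division genes had opposite signs in these pairs: of 39 G2 and mitosis genes 1 was higher in replicates 1 and 2 (median 1.01) and 33 were lower in replicates 3 and 4 (median −1.97), and of 41 S phase genes 6 were higher (median 0.76) and 22 lower (median −1). Over all 4 replicates edgeR called none of either list (medians −0.34 and 0.02, camera adjusted p = 0.133 and 0.873, fry adjusted p = 0.72 and 0.911). On soft matrix camera also called MRTF/SRF targets (median 0.34, adjusted p = 0.0113), of which 5 were higher and 1 lower (5 and 1 adjusted over the list alone). It called cross-linking genes (median 0.35, adjusted p = 0.0422), with 7 higher and 5 lower (12 and 5 adjusted over the list alone). Cholesterol synthesis (median 0.44, adjusted p = 0.0343) had 2 higher (8 adjusted over the list alone) and ribosomal proteins (median −0.17, adjusted p = 0.0343) had 0 changed. These 4 lists had adjusted p = 0.967, 0.967, 0.974 and 0.974 with an estimated correlation. The cholesterol median was −0.11 in replicates 1 and 2, with 0 genes higher and 1 lower, and in replicates 3 and 4 it was 0.79, with 10 higher. The cross-linking median was 0 and 0.62 in these pairs, that of MRTF/SRF targets 0.33 and 0.43 and that of ribosomal proteins −0.15 in both. Without Coronary-Stiff replicate 4 cholesterol synthesis had adjusted p = 0.0532 and cross-linking genes 0.0557.

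On stiff matrix 13 of 29 MRTF/SRF targets were higher in coronary cells (19 adjusted over the list alone; median 0.68, adjusted p = 3.03e-06). Of 28 contractile genes 12 were higher and 1 lower (17 and 3 adjusted over the list alone; median 0.83, adjusted p = 0.0015), among them ACTA2 by 2.30 ± 0.477, and by 1.44 without Coronary-Stiff replicate 4. Also higher were 4 of 6 epithelial markers (5 adjusted over the list alone; median 1.55, adjusted p = 0.000164), such as KRT18 by 1.58 ± 0.301, and 2 of 32 histones (0 adjusted over the list alone; median 0.28, adjusted p = 0.0434). In this order the lists had adjusted p = 0.605, 0.721, 0.425 and 0.853 with an estimated correlation. Without Coronary-Stiff replicate 4 the contractile list had adjusted p = 0.0608 with 9 genes higher and 2 lower, and the MRTF/SRF list 7 higher and 1 lower. The contractile median was 0.18 in replicates 1 and 2, with 1 gene higher and 3 lower, and in replicates 3 and 4 it was 1.24, with 17 higher and 2 lower. The MRTF/SRF median was 0.23 and 1.22 in these pairs and the epithelial one 0.76 and 2.06. ACTA2 differed by 0.57 in replicates 1 and 2 (adjusted p = 0.499) and by 3.27 in replicates 3 and 4.

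In all, 1980 genes (11.2%) differed between arteries on soft matrix, 941 higher and 1039 lower in coronary cells, and 1978 on stiff matrix, 1034 higher and 944 lower. In the same direction on both matrices were 522 higher genes (55 expected of independent lists) and 586 lower ones (55 expected). By the rule, PDPN (ENSG00000162493.12), a membrane protein gene of mesothelial and lymphatic cells, had 1.09 ± 0.163 CPM in aortic and 54.9 ± 14.2 in coronary cells on soft matrix, and DIO2, a thyroid hormone deiodinase gene, 242 ± 33.4 and 4.22 ± 1.05 CPM. LTF, the lactoferrin gene, was higher by 6.05 ± 1.35, and by 3.49 without Coronary-Soft replicate 4. On soft matrix 957 genes passed within replicates 1 and 2 and 1979 within replicates 3 and 4, 658 in both in the same direction and 12 in opposite directions. On stiff matrix 749 and 1923 passed, 563 in both in the same direction. At an unadjusted p under 0.05, 4007 genes passed on soft and 4017 on stiff matrix.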

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

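The tests of endothelial markers and of cholesterol synthesis and the values by replicate pairs were chosen after the results were seen, while those on the direction of long non-coding RNAs were written before.

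Long non-coding RNAs called in coronary cells were lower on stiff matrix in 71.8% of cases, against 49.1% of called coding genes. In coronary cells reads from overlapping genes are argued against as the only cause. Intergenic RNAs alone were lower in 66.7% of 240 called (Fisher exact p = 7.87e-08 against coding genes), and antisense RNAs in 72.9% of 207. A smaller share of reads outside exons is likewise argued against. With that share as a term 65.7% of 271 called long non-coding RNAs were lower (48.9% of coding genes, Fisher exact p = 7.8e-08). That term cut the coronary calls from 7375 to 4628 genes. Both tests used all called coding genes as reference, so they do not set either explanation apart from low abundance. Low abundance of long non-coding RNAs may account for most of the pattern, since coding genes weighted to the same abundance were lower in 68.4% of cases. In aortic cells 60.9% of called long non-coding RNAs and 62.5% of coding genes weighted in this way were lower, and of 149 called intergenic RNAs 56.4% (52.3% of coding genes, Fisher exact p = 0.359). Within aortic replicates 1 and 2, 92 of the class were higher and 121 lower, but within replicates 3 and 4, 46 and 38. Within coronary replicates 1 and 2 these counts were 50 and 72, and within replicates 3 and 4, 146 and 339. A response of the class to stiffness, which the design names, stays open: its median was −0.31 (camera adjusted p = 0.0243, and adjusted p = 0.452 with an estimated correlation), and no test set it apart from abundance.

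Of 11 endothelial markers 6 were higher in coronary than in aortic cells on soft matrix, and none of the 11 is in another list. The median of all 11 was 0.96 within replicates 1 and 2 and 0.93 within replicates 3 and 4. Endothelial cells in the coronary cultures, which no sort or gate in the labels would have removed, could be a candidate source and stay open, since the median of all 11 was 0.60 but single markers lay between −0.52 and 2.46. On soft matrix VWF and EMCN, abundant in endothelial cells, had 2.87 and 8.54 CPM in aortic and 2 and 9.3 CPM in coronary cells. On stiff matrix VWF and EMCN had 2.45 and 3.52 CPM in aortic and 1.34 and 3.1 CPM in coronary cells. Of the 11 markers 8 had a mean of at least 1 CPM in aortic cells on soft matrix. The artery of origin, named by the design, stays open, as does the person each culture came from, which was not tested.

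Cholesterol synthesis genes were lower on stiff matrix in coronary cells, with a median of −0.73. A few genes taking a larger share of the counts on stiff matrix are argued against, since they would lower all other genes alike, while with library size only the median was −0.80 and lay by −0.70 from that of all genes (−0.10). The median was −0.05 within replicates 1 and 2 (3 genes higher and 2 lower) and −1.14 within replicates 3 and 4 (2 higher and 14 lower), and the labels do not say what replicates of a number share. An effect of stiffness on sterol synthesis in coronary cells, named by the design, stays open, with camera adjusted p = 0.0459, fry adjusted p = 0.156 and adjusted p = 0.725 with an estimated correlation.

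In a test of the difference of the stiffness response between arteries 2 genes passed, LPAR1 with 1.30 and NXN with −2.22, but 0 genes passed with a replicate block within each artery or when any one of 11 of the 16 libraries was left out. Coronary libraries of the same number, soft and stiff, deviated together from their group means. By camera 17 lists passed, although none did with an estimated correlation (lowest adjusted p = 0.613) or by fry, and 10 did without Coronary-Stiff replicate 4. Of the lists named here, those with a lower response (coronary minus aortic) were matrix structural (adjusted p = 1.2e-12), cholesterol synthesis (2.05e-07), TGF-beta and BMP (2.35e-05), cross-linking (0.000175) and inflammatory genes (0.000188). Lower in this sense too were fatty acid synthesis (0.0122), S phase (0.0212), developmental (0.0278) and mitochondrially encoded genes (0.0427) and the long non-coding class (0.00532). Lists with a higher response (coronary minus aortic) were ribosomal proteins (adjusted p = 1.84e-07), epithelial (0.000714), contractile (0.0136), MRTF/SRF (0.0145), hypoxia and glycolysis (0.0278) and interferon-stimulated genes (0.0427). Their median differences, in the same orders, were −0.42, −0.52, −0.25, −0.28, −0.30, −0.25, −0.30, −0.19, −0.23 and −0.14, and 0.19, 0.95, 0.43, 0.29, 0.34 and 0.27. The contractile list had adjusted p = 0.935 without Coronary-Stiff replicate 4, MRTF/SRF 0.706 and S phase 0.905. The median differences in replicates 1 and 2, in the same orders, were −0.13, −0.16, 0.06, −0.08, 0.03, −0.18, −0.80, −0.05, −0.08 and −0.07, and 0.02, −0.02, −0.17, −0.23, 0.10 and 0.07. In replicates 3 and 4 they were −0.73, −0.93, −0.62, −0.45, −0.48, −0.33, 0.44, −0.34, −0.26 and −0.22, and 0.36, 1.55, 0.81, 0.68, 0.54 and 0.44.

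A library far from the other 3 of its group was found in 5 of 40 groups for library measures and in 19 of 207 groups for genes, where chance gives about 1 in 20 groups of normally distributed values. Values here were rounded, and some of the gene values below lie under the floor of 0.071 CPM, so this rate is only a guide. Aortic-Stiff replicate 2 had 25770 genes with a count (others 24415 to 24463). In Aortic-Soft replicate 3, 7.92% of reads fell outside annotated exons (others 10.47% to 10.84%). Coronary-Soft replicate 1 had 0.22% mitochondrial counts (others 0.24%) and 92.97% counts in coding genes (others 94.72% to 94.81%). The 10 highest genes of Aortic-Stiff replicate 3 took 6.73% of counts (lowest of the others 7.84%).

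For genes, values in CPM are followed by those of the other 3 libraries. Aortic-Stiff replicate 4 had CCL1 at 0.78 (0.04 to 0.07), PMCH at 10.4 (0.83 to 2.39), AL157702.2 at 0.80 (0.12 to 0.19) and LINC01111 at 0.91 (3.06 to 3.4). Coronary-Stiff replicate 4 had NPPB at 23.7 (1.31 to 3.34), MGAM at 4.45 (1.28 to 1.8) and P4HA3-AS1 at 0.03 (0 in each). Coronary-Soft replicate 4 had LTF at 148 (6.05 to 9.5), TREM1 at 10.3 (0.4 to 1.55) and CYP26A1 at 0.04 (0 in each). Coronary-Stiff replicate 1 had ZCCHC12 at 2.52 (0.57 to 0.82), CST2 at 1.13 (0.26 to 0.31) and CXCR4 at 0.30 (0 to 0.03). Coronary-Soft replicate 1 had CNTN4 at 0.17 (0.04 to 0.06) and AC116036.2 at 0.23 (0.36 to 0.38). LPAR1 was at 158 in Aortic-Soft replicate 3 (110 to 113), AL353751.1 at 0.27 in Aortic-Soft replicate 4 (0.13 to 0.14), P4HA3-AS1 at 0.07 in Aortic-Soft replicate 1 (0.45 to 0.5) and LINC01050 at 0.03 in Coronary-Stiff replicate 2 (0 in each).

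Other splits of the libraries into groups of the same size gave fewer called genes than the real grouping in aortic cells and between arteries. In aortic cells 1 of 35 splits, the real one, reached 5292 genes (highest other 0) and 330 long non-coding RNAs (0). Between arteries 1 of 35, the real one, reached 1980 genes on soft (0) and 1978 on stiff matrix (53). A share of 1 in 35 is under 0.05, which argues against a chance split if the libraries are exchangeable. It is also the smallest share that 35 splits can give. Between arteries the splits cannot tell the artery from the person each culture came from. In coronary cells 1 of 35 splits, the real one, reached 7375 genes (highest other 1248) and 553 long non-coding RNAs (53), and the highest split exchanged Coronary-Stiff replicate 4 and Coronary-Soft replicate 2. As coronary numbers were taken to pair the libraries, on the data alone, the like splits are the 8 that part all 4 pairs. These are too few for a share under 0.05, and the highest other of them had 0 genes and 0 long non-coding RNAs. The remaining splits put at least 1 pair on one side. Of 100 splits, 1 reached the 9158 genes of the mean, the 4412 genes of both arteries and the 236 long non-coding RNAs of both (highest other 0 for each). Of these 100, 18 part all coronary pairs, also too few for such a share. For the difference of responses, 3 of 100 reached the 2 genes called, and the highest other had 4175. That split came close to exchanging stiff and soft in coronary cells, so it points to a structure of the samples, the response shared by both arteries.

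For the number of lists past the threshold by camera, chance cannot be excluded. As many lists were reached in 13 of 35 splits for aortic cells (12 lists, highest other 16), 3 for coronary cells (20, highest other 20), 24 between arteries on soft (7, highest other 15) and 33 on stiff matrix (7, highest other 19). Of 100 splits, 19 reached the 16 lists of the mean (highest other 21) and 17 the 17 lists of the difference of responses (highest other 20).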

How the results depend on the processing

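Chosen after seeing the data were the term for replicates 1 and 2 against 3 and 4, the list tests with a replicate block within each artery and those without Coronary-Stiff replicate 4. With a library left out, genes changed by stiff matrix numbered 3824 to 6303 in aortic cells, 6229 to 7487 in coronary cells, 8511 to 9493 for the mean and 3384 to 4997 in both arteries. Genes differing between arteries numbered 1534 to 2563 on soft and 1357 to 2016 on stiff matrix. Under the other settings the ranges were 4365 to 5873, 6148 to 7874, 8187 to 9562, 3546 to 4865, 1762 to 2474 and 1388 to 2472. All these counts stayed within 1.5 times the main count.

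Long non-coding RNAs changed by stiff matrix numbered 211 (without Aortic-Stiff replicate 1) to 405 (without Coronary-Stiff replicate 4) in aortic cells, 426 to 577 in coronary cells and 159 to 251 in both, with a library left out. With the stricter filter the coronary count was 316, as fewer of these low RNAs were tested.

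Genes whose stiffness response differs between arteries numbered 2 in the main analysis, 1 with library size only, 5 without the low-count filter, 41 by DESeq2, 0 with a replicate block within each artery, and 0 to 8 with a library left out (0 without 11 of the 16 libraries, 8 without Coronary-Stiff replicate 1). In the simulated data DESeq2 made 18 false calls for this difference and edgeR 2, while DESeq2 recovered 36% and 73% of changes and edgeR 22% and 67%. What moved the count between settings was not tested.

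With an estimated correlation the lists past the threshold numbered 0 in aortic cells, 0 in coronary cells, 0 for the mean, 0 for the difference of responses and 1 between arteries on soft and 1 on stiff matrix, since that setting widens the error of each list by its own correlation. Fry, which tests a list by itself and not against other genes, called 25 lists for the mean and 0 for the difference of responses. Without Coronary-Stiff replicate 4 camera called 10 lists for the difference of responses. With a replicate block across all 16 libraries it called 4 lists between arteries on soft matrix. For these last 2 the cause was not tested.

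With a replicate block across all libraries, genes changed by stiff matrix in aortic cells numbered 5770 and genes changed by stiff matrix in coronary cells 7847, and with a block within each artery 5494 and 7542. In coronary cells COL1A1 and ELN passed with the latter block and LINC02345 did not. Libraries of the same number had correlated residuals above 0.1 in 13 of 24 pairs (−0.159 to 0.354), and the labels do not say what they share. Of up to 352 results for named genes per setting 0 reversed under the settings run, and 352 kept their side of the threshold with RLE factors, 334 without the low-count filter and 338 without Aortic-Stiff replicate 1. Upper-quartile factors moved the median of all genes in coronary cells to −0.108. In coronary cells a group mean of 3 counts per library was 0.071 CPM, and 9 HOX genes on soft and 7 on stiff matrix had a mean at or under it.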

Other observations

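The list test with a replicate block was chosen after the result was seen, the other tests were not, and the genes named here were picked from their lists after their values were seen. Of 17 G1 regulators 7 rose and 3 fell in aortic cells (7 and 4 adjusted over the list alone; median 0.29, adjusted p = 0.0575) and 7 rose and 4 fell in coronary cells (7 and 4 adjusted over the list alone; median 0.40, adjusted p = 0.378). The ubiquitin ligase gene SKP2 rose by 1.57 ± 0.281 in coronary cells, and the cell cycle inhibitor gene CDKN2B fell by 1.19 in aortic and 2.07 in coronary cells. Of 29 hypoxia and glycolysis genes 4 rose and 4 fell in aortic cells (4 and 4 adjusted over the list alone; median −0.02, adjusted p = 0.86), with a median just above 0 under library size only. In coronary cells 11 rose and 5 fell (13 and 7 adjusted over the list alone; median 0.31, adjusted p = 0.402), with the glycolytic enzyme gene ENO1 up by 1.48 ± 0.195 and the peptide gene ADM at −1.36 ± 0.217. Of 35 integrins and focal adhesion genes 11 fell and 3 rose in aortic cells (11 and 3 adjusted over the list alone; median −0.12, adjusted p = 0.256). In coronary cells 12 fell and 12 rose (12 and 13 adjusted over the list alone; adjusted p = 0.354), where the median was 0.00, the mean −0.32 and the test pointed down. The collagen receptor gene ITGA1 fell by 1.25 ± 0.228 and 2.72 ± 0.241 in the 2 arteries.

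Of 26 interferon-stimulated genes 4 rose and 7 fell in aortic cells (4 and 7 adjusted over the list alone; median −0.27, adjusted p = 0.46) and 4 rose and 4 fell in coronary cells (4 and 4 adjusted over the list alone; adjusted p = 0.801), where the median was −0.30, the mean −0.06 and the test pointed up. OAS3, an antiviral enzyme gene, rose by 1.66 and 1.64, and MX1 fell by 1.39 and 0.68. Of 20 genes of unfolded protein and amino acid stress 5 fell and 1 rose in aortic cells (5 and 1 adjusted over the list alone; median −0.07, adjusted p = 0.263) and 7 fell in coronary cells (7 adjusted over the list alone; median −0.20, adjusted p = 0.0723, and 0.0274 with a replicate block within each artery), among them the chaperone gene HSP90B1 by 1.16 ± 0.183 and 1.13 ± 0.183. With an estimated correlation camera called 0 lists in coronary cells. The coronary median of this stress list was −0.45 within replicates 1 and 2 (0 higher and 6 lower) and 0.03 within replicates 3 and 4 (6 higher and 7 lower). Of 15 mitochondrially encoded transcripts 0 changed in aortic cells by edgeR (0 adjusted over the list alone; median 0.15, camera adjusted p = 0.584, fry 0.678) and 1 fell in coronary cells (0 adjusted over the list alone; median −0.04, adjusted p = 0.617).

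Other lists did not pass for stiff against soft matrix by camera in either artery. HOX genes (19) had 2 lower in aortic cells (median −0.07, adjusted p = 0.545) and 1 higher and 2 lower in coronary cells (0 and 1 adjusted over the list alone; median −0.15, adjusted p = 0.825). Of 11 endothelial markers 1 rose and 3 fell in aortic cells (median 0.13, mean −0.12, adjusted p = 0.596) and 3 rose and 1 fell in coronary cells (median −0.27, adjusted p = 0.826). Pericyte markers (7) had 2 up and 2 down in each artery (3 and 2 adjusted over the list alone in aortic cells), with median −0.03, adjusted p = 0.886 and the test pointing up in aortic cells, and median 0.26, mean −0.02 and adjusted p = 0.826 in coronary cells. PDGFRB, a growth factor receptor gene of pericytes and smooth muscle, fell by 1.22 and 2.05. Among leukocyte markers (5) 1 rose in each artery, with median 0.00, mean 0.29 and adjusted p = 0.581, then median −0.11, mean 0.10 and adjusted p = 0.71, and the aortic median turned from below to above 0 with RLE factors or library size only. Adipocyte markers (3) had 1 up in each (median 0.19, adjusted p = 0.46; median 0.62, adjusted p = 0.602), as did cardiomyocyte markers (3; median 0.76, adjusted p = 0.545; median 1.58, adjusted p = 0.41). Of 4 neural and glial markers 1 fell in aortic cells (2 adjusted over the list alone; median −0.87, adjusted p = 0.154) and 2 in coronary cells (median −1.07, adjusted p = 0.114), with NCAM1, an adhesion molecule gene, among them.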
